A study of Mus musculus with 24 samples.

How the data were processed

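Polyadenylated RNA from mouse spinal cord was sequenced in 24 libraries, 15 from pups at postnatal day 7 (P7) and 9 from mice at 13 weeks of age. Per the labels' protocols, total RNA was extracted with the RNeasy Mini Kit, checked on a NanoDrop spectrophotometer and a Bioanalyzer, and made into libraries with Illumina's TruSeq stranded mRNA kit. The antisense oligonucleotides (ASOs, short synthetic strands that bind a chosen RNA) were injected into the cerebral ventricles on postnatal day 1, per the labels' protocols. By sample, that day is recorded for AR-ASO and Rest4-ASO but not for the scramble-ASO. The 8 groups held 3 libraries each. The labels do not say that replicates were separate animals, so p-values here measure only the spread between these samples, which may be technical.

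The authors deposited 4 tables in TPM, a unit that divides read coverage by transcript length and scales each library to a total of 1000000. FastQC, Trimmomatic, HISAT2, StringTie and the mouse genome build mm10 are named, without versions, per the submitters' processing notes. The annotation release, the use of read strand in quantification and the treatment of reads from the human transgene are not given in the sources used here. Each deposited table listed the same 45777 gene symbols, of which 40686 matched a symbol in the RefSeq table used here. The TPM columns summed to between 999710 and 1000000. TPM keeps no read number, so the sequencing depth of each library is unknown and no counting interval or detection floor was computed. Between 15694 and 16286 features per library stood at 1 TPM or more, and the 10 most abundant features took 11.6% to 22.0% of the total. No 2 libraries of a group were duplicates of each other. Xist stood at no more than 0.0714 TPM and the Y-linked Ddx3y at no less than 27.3 TPM in these mouse libraries.

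The first table held the P7 wild-type (WT), AR-97Q and AR-ASO treated AR-97Q libraries, the second the P7 scramble-ASO and Rest4-ASO treated AR-97Q libraries, the third the 13-week WT and AR-97Q libraries, and the fourth the 13-week AR-ASO treated AR-97Q libraries. Tests between groups stayed within a table. The 13-week AR-ASO libraries had no comparison group in their own table, so table and treatment were confounded and their levels were set beside the other 13-week values without a test. The difference of the AR-97Q effect between the ages was tested as a contrast of both within-table effects.

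The design fixed before the data were examined called for a count-based test where counts were deposited and for limma on log values where they were not. Because the tables held TPM, each comparison was fitted with limma (version 3.58.1, R version 4.3.3, data.table version 1.17.8, statmod 1.5.0) on log2(TPM + 1), with group means, a spread trend over expression and Benjamini-Hochberg adjustment at 0.05. Features at 1 TPM or more in at least 3 libraries of the fit were kept. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes near 1 TPM, and errors beside them are standard errors (SE). The 3 comparisons among P7 WT, AR-97Q and AR-ASO treated AR-97Q shared one fit of 9 libraries. Single levels of Ar and Rest were also compared with exact 2-sided permutation tests, for which 0.1 is the smallest possible p with 3 libraries against 3.

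The 43 gene lists, with 821 genes of which 799 were in the tables, were written before the data were examined. They cover neuronal, glial, vascular and non-neural cell markers, and pathways. A list with at least 5 measured genes was tested with limma's camera, which compares the list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list was also tested with a correlation estimated from the data and with fry, which asks whether its genes move in one direction on balance. No list call in any of the 6 tested comparisons held with the estimated correlation, so each list call rests on the preset value. Counts of list members are given over all genes tested and adjusted over the list alone.

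The rule for named genes was fixed before the data were examined. It takes Ar and Rest, and up to 8 higher and 8 lower genes of largest fold change at an adjusted p under 0.05. These need a mean of at least 1 TPM and groups that do not overlap, and predicted genes, haemoglobin and mitochondrial genes and pseudogenes are left out. The rule adds up to 4 called members per list, and where fewer than 3 genes pass, the 5 genes of smallest p, named as not past the threshold. For lists without called members it allows the first 2 listed genes. Those examples are given here for the 5 called lists of largest median in each comparison and for the REST target and motor neuron lists, a restriction made after the values were seen and applied whatever the examples showed. Genes called for the difference between ages are also given at each age, and as TPM alone where they were below the filter at that age. Ndufc1 and Pisd-ps1 in the Rest4-ASO comparison and Calcb at 13 weeks fall outside the rule and were chosen after their values were seen.

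Coordinates are those of the GRCm38.p6 annotation, the assembly that mm10 stands for, 1-based. Correlations of fold changes between comparisons are across genes, which are not independent replicates. Where 2 comparisons shared libraries, 100 sets of simulated unchanged groups gave the values that shared libraries alone produce, and the shared libraries were divided between the comparisons in each of 6 ways.

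The fits were tested on simulated values drawn for each gene independently from its real mean and spread. The 200 changed genes per comparison were divided among log2 fold changes of 0.5, 1 and 2. Correlation between genes and shifts of whole libraries were not simulated, so recovery in the real data may be lower. At a simulated log2 fold change of 1, the fits recovered 97.0% of changed genes for P7 AR-97Q against WT (16447 genes), 92.5% for P7 AR-ASO against AR-97Q and 95.5% for P7 AR-ASO against WT. They recovered 98.5% for Rest4-ASO against scramble-ASO (16012 genes), 85.1% for 13-week AR-97Q against WT (16043 genes) and 62.7% for the difference between ages (17121 genes). At 0.5 the shares were 61.2%, 59.7%, 58.2%, 56.7%, 20.9% and 13.4% in that order.

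Alternatives covered quantile normalization, no filter, a filter of 5 TPM in every library of a group, a pseudocount of 0.1, a replicate block, a fold change of at least 1.5, and the removal of mitochondrial, haemoglobin and ribosomal protein genes. Each library was also left out in turn, and the 3-group fits were repeated on the compared groups alone. An adjusted p under 0.1, array weights and the removal of Mir and Snor features were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with numpy 2.4.6.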

Results

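The spinal cord was profiled in WT mice and in AR-97Q mice, a model of spinal and bulbar muscular atrophy that carries an androgen receptor with an expanded polyglutamine tract. At P7 there were 3 libraries each of WT, AR-97Q, AR-97Q given an ASO against the androgen receptor (AR-ASO), AR-97Q given a scramble-ASO and AR-97Q given an ASO against Rest4. Rest4 is a splice variant of Rest, the gene of a repressor of neuronal genes. At 13 weeks there were 3 libraries each of WT, AR-97Q and AR-ASO treated AR-97Q. Values are TPM as deposited, the depth behind them is unknown, and means are given ± SD with n = 3 unless SE is stated.

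Ar, the mouse androgen receptor gene on chromosome X (98148757 to 98323218), was near the filter at P7. How reads of the human transgene were treated is not given, so the Ar values may or may not include them. It stood at 0.748, 0.806 and 1.23 TPM in the WT libraries, at 1.53, 1.67 and 1.78 TPM in AR-97Q, and at 0.713, 1.08 and 0.717 TPM in AR-ASO treated AR-97Q. AR-97Q did not overlap with WT or with AR-ASO treated AR-97Q, and each difference gave an exact permutation p of 0.1, the smallest possible with n = 3 per group. Across all genes tested with limma neither difference passed (adjusted p = 0.233 and 0.292). Ar stood at 1.52 ± 0.20 TPM after scramble-ASO and 1.41 ± 0.23 TPM after Rest4-ASO. At 13 weeks it stood at 6.62 ± 0.065 TPM in WT, 7.60 ± 0.52 TPM in AR-97Q and 6.62 ± 0.41 TPM in AR-ASO treated AR-97Q, the last from a separate table and without a test. Rest, on chromosome 5 (77265494 to 77286432), stood at 5.50 ± 0.20, 5.33 ± 0.46 and 5.25 ± 0.49 TPM in P7 WT, AR-97Q and AR-ASO treated AR-97Q, and at 4.42 ± 0.795 TPM after scramble-ASO and 4.45 ± 0.17 TPM after Rest4-ASO. The tables give 1 value per gene, so the Rest4 variant that the ASO targets was not measured.

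**Figure D1:**
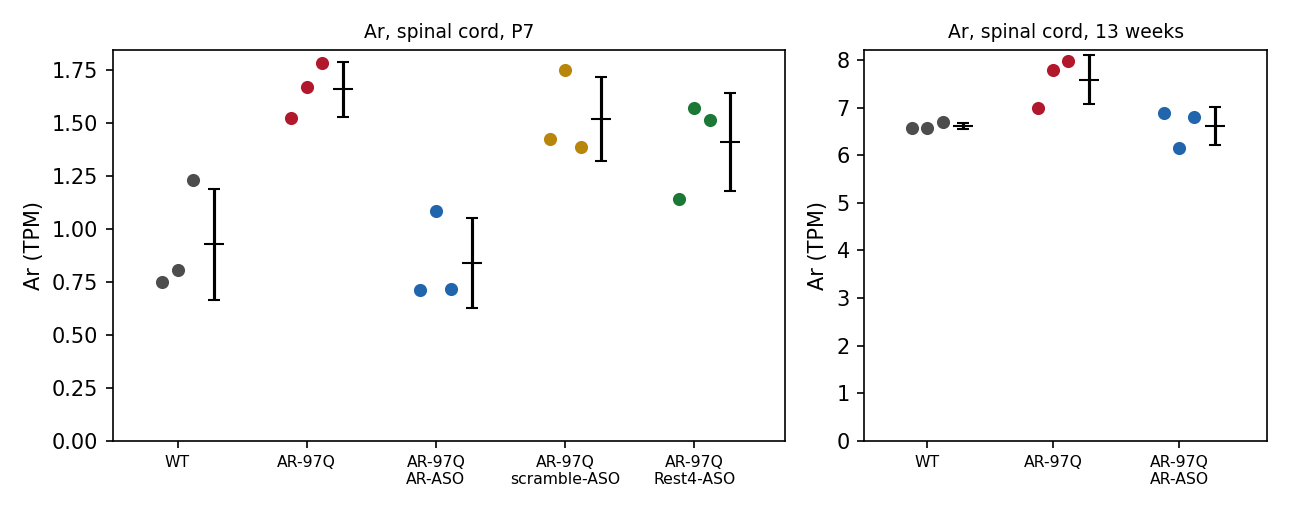
Ar in TPM (y axis) in each library (points) by group (x axis) at P7 (left) and 13 weeks (right), with the mean and SD of 3 libraries beside the points. At P7 the AR-97Q libraries sit at 1.53 to 1.78 TPM, above all WT and AR-ASO libraries; the 13-week AR-ASO libraries come from a separate table.

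Myelin genes were lower in the P7 AR-97Q spinal cord than in WT. All 25 measured genes of myelinating oligodendrocytes, the cells that wrap central axons, had negative fold changes, with a median of −0.70 on the log2 scale. Mbp, a main protein of compact myelin, stood at 12722 ± 1078 TPM in WT and 6605 ± 836 TPM in AR-97Q (log2 fold change −0.95 ± 0.17 SE). Plp1, the other main myelin protein gene, stood at 3428 ± 110 and 2112 ± 407 TPM (−0.72 ± 0.17 SE). The groups did not overlap for either gene. In scramble-ASO treated AR-97Q pups, from a separate table, Mbp took 0.877%, 1.404% and 0.583% of total TPM. Those libraries ran from inside the untreated AR-97Q range (0.5695% to 0.7337%) to above all WT libraries (1.167% to 1.383%). The list was called by limma's camera (adjusted p = 3.49e-41), and all 25 genes passed when adjusted over the list alone, but none over all genes (adjusted p = 0.193 with an estimated correlation).

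Lists of other glial and of vascular cells also fell relative to all genes tested, whose own median was +0.09. Astrocyte markers had a median of −0.20, with 15 of 17 negative and 8 lower when adjusted over the list alone; their first 2 genes went apart, with the water channel gene Aqp4 at −0.28 ± 0.09 SE and Aldh1l1 at +0.02 ± 0.09 SE (−0.05 under quantile normalization). Oligodendrocyte precursor markers had a median of −0.19 (12 of 15 negative), with the growth factor receptor gene Pdgfra at −0.08 ± 0.09 SE and Cspg4 at −0.34 ± 0.14 SE. Endothelial and mural cell markers (median −0.16, 18 of 18 negative), meningeal fibroblast genes (−0.19, 1 gene lower over the list alone) and cholesterol biosynthesis genes (−0.15, 4 lower over the list alone) fell as well. Each of these 5 lists was called by camera (adjusted p from 4.48e-12 to 0.000369) and none was called with an estimated correlation (adjusted p = 0.193, or 0.3 for cholesterol biosynthesis). The cholesterol median was −0.24 without AR-97Q replicate 1 and −0.10 without AR-97Q replicate 2. Mitochondrially encoded genes had a median of −0.21 (adjusted p = 5.17e-08, and adjusted p = 0.346 with an estimated correlation; 0 of 13 passed over the list alone), with ND1 at −0.25 ± 0.13 SE and ND2 at −0.26 ± 0.13 SE. That direction turned under quantile normalization, where the median was +0.03 and ND2 stood at +0.20. Bone and cartilage genes (−0.16), disease-associated microglia genes (−0.05), immediate early genes (−0.01) and homeostatic microglia markers (−0.001) were also called lower (adjusted p = 0.0192, 0.0093, 0.0093 and 0.0141, and adjusted p = 0.453, 0.193, 0.346 and 0.574 with an estimated correlation), and each of these 4 calls ended in single fits without 1 library. The bone list ended without WT replicate 2 (adjusted p = 0.059) or AR-97Q replicate 1 (0.0558), and the immediate early list without WT replicate 1 (0.0578) or AR-97Q replicate 1 (0.0699). The disease-associated microglia list ended without WT replicate 1 (0.115) or AR-97Q replicate 2 (0.0857), and the homeostatic microglia list without WT replicate 1 (0.197) or AR-97Q replicate 2 (0.0762). In fits without 1 library the bone median was as small as −0.058 (AR-97Q replicate 1), and that of disease-associated microglia genes ran from −0.10 (AR-97Q replicate 1) to −0.024 (WT replicate 1; −0.034 without AR-97Q replicate 2). The immediate early median ran from −0.11 (WT replicate 2) to +0.049 (AR-97Q replicate 1) and that of homeostatic microglia markers from −0.024 (AR-97Q replicate 2) to +0.019 (AR-97Q replicate 3), each moved by other libraries in between.

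Of 11 neuronal lists, 2 were called higher in P7 AR-97Q, REST target and synaptic vesicle genes. REST target genes, neuronal genes with a binding element for the Rest protein, had a median of +0.18, with 42 of 44 positive and 2 higher over the list alone (adjusted p = 0.00837 by camera, and adjusted p = 0.739 with an estimated correlation). Their first listed genes, Syn1 and Syp of synaptic vesicles, stood at +0.04 ± 0.14 SE (−0.02 under quantile normalization) and +0.19 ± 0.09 SE. Genes of synaptic vesicles and release had a median of +0.17 (32 of 35 positive, 1 over the list alone, adjusted p = 0.0141, and adjusted p = 0.739 with an estimated correlation). Proliferation genes had a median of +0.20 (19 of 20 positive, 0 over the list alone, adjusted p = 0.0093, and adjusted p = 0.695 with an estimated correlation), with Mki67 at +0.20 ± 0.10 SE and Top2a at +0.30 ± 0.10 SE. Without WT replicate 1 the REST target median was +0.05 (adjusted p = 0.878) and the synaptic vesicle median +0.02, with camera's direction turned. Without AR-97Q replicate 2 the REST target call ended (adjusted p = 0.0596), and without WT replicate 3 the proliferation call ended (adjusted p = 0.161). Motor neuron markers were not called (median +0.05, with camera's direction lower, adjusted p = 0.272); Chat and Slc18a3, genes of acetylcholine synthesis and its vesicular transport, stood at −0.13 ± 0.14 SE and −0.07 ± 0.13 SE.

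No single gene passed the threshold for P7 AR-97Q against WT by limma (0 of 16447, smallest adjusted p = 0.133). At an unadjusted p under 0.05, 2688 genes passed, 2070 higher and 618 lower. In 3777 genes (23.0%) the groups did not overlap, against 10% on average by chance. Here and below, that 10% is a mean over splits of the libraries. Genes vary together, and the spread of the share over other splits was not computed, so the share does not test chance. Leaving out WT replicate 3 gave 3 calls. The 5 genes of smallest p, none past the threshold, were Ntng2 (−0.86 ± 0.12 SE), Gal3st1 (−0.63 ± 0.09 SE), Ntsr2 (−0.57 ± 0.09 SE), Rragb (+0.84 ± 0.14 SE) and Mlf1 (+0.59 ± 0.10 SE). Gal3st1 encodes the enzyme that makes the myelin lipid sulfatide, and Ntng2 a membrane-anchored netrin.

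**Figure D2:**
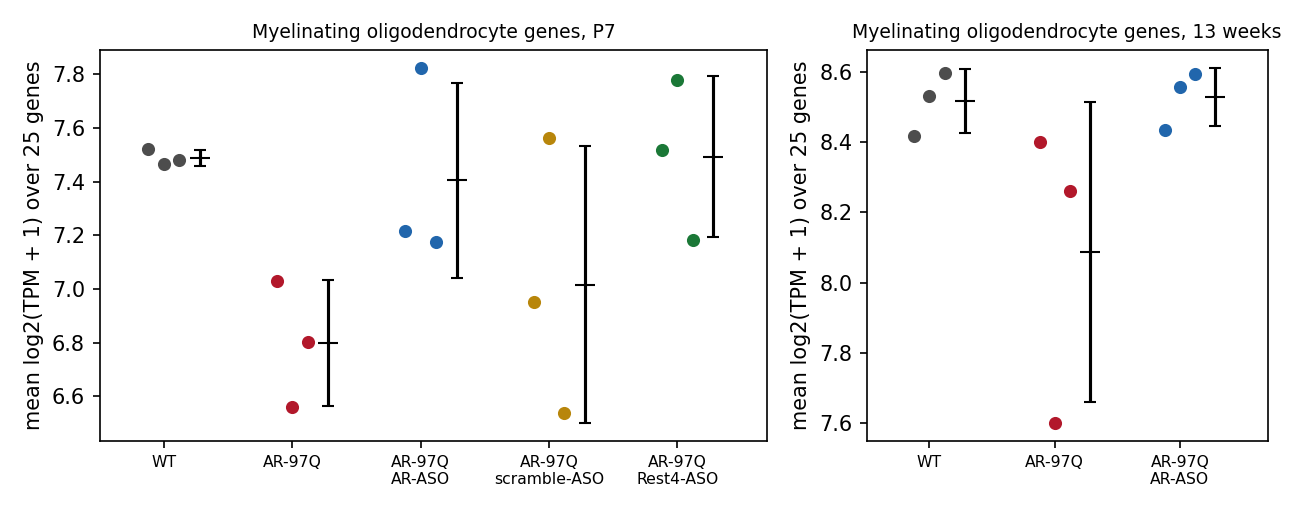
Mean log2(TPM + 1) over the 25 genes of the list of myelinating oligodendrocyte genes (y axis) in each library (points) by group (x axis) at P7 (left) and 13 weeks (right), with mean and SD of 3 libraries; y axes differ. At P7 the WT libraries sit at 7.46 to 7.52 and the AR-97Q libraries at 6.56 to 7.03.

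Treatment with AR-ASO went with higher myelin genes than in untreated AR-97Q at P7. The labels name no ASO for the AR-97Q and WT pups compared with it. In both AR-ASO comparisons, an effect of the AR-ASO sequence thus cannot be told apart from one of injection or of any ASO. The myelinating oligodendrocyte list had a median of +0.63, with 24 of 25 genes positive and 23 higher over the list alone but 0 over all genes (adjusted p = 5.13e-41 by camera, and adjusted p = 0.48 with an estimated correlation). Mbp stood at 11385 ± 3140 TPM after AR-ASO (+0.76 ± 0.17 SE) and Plp1 at 3225 ± 862 TPM (+0.60 ± 0.17 SE). This comparison and that of AR-97Q against WT use the same AR-97Q libraries, so their opposite myelin values are not independent. The share of Mbp in scramble-ASO treated AR-97Q libraries spread from inside the untreated AR-97Q range to above all WT libraries. Mitochondrially encoded genes had a median of +0.31 (13 of 13 positive, 7 over the list alone, adjusted p = 3.96e-14, and adjusted p = 0.48 with an estimated correlation), with ND1 at +0.34 ± 0.13 SE and ND2 at +0.39 ± 0.13 SE; that call ended under quantile normalization (adjusted p = 0.835). Oligodendrocyte precursor markers (+0.12), with Pdgfra at −0.10 ± 0.09 SE and Cspg4 at +0.02 ± 0.14 SE, and cholesterol biosynthesis genes (+0.10) were also called higher (adjusted p = 0.00012 and 3.4e-08, and adjusted p = 0.48 with an estimated correlation for both), with 0 genes over either list alone. Without AR-ASO replicate 2 the precursor median was +0.046 and the mitochondrial median +0.18. The cholesterol median was +0.18, +0.056 and +0.062 without AR-97Q replicates 1, 2 and 3, and +0.060 without AR-ASO replicate 2.

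Motor neuron markers had a median of −0.23 after AR-ASO against AR-97Q (18 of 23 negative, 0 over the list alone, adjusted p = 0.0284, and adjusted p = 0.764 with an estimated correlation). Chat stood at −0.23 ± 0.14 SE and Slc18a3 at −0.44 ± 0.13 SE. The call ended without AR-97Q replicate 1 (adjusted p = 0.178), AR-ASO replicate 1 (0.0724) or AR-ASO replicate 2 (0.061), where the median was −0.15. Proliferation genes had a median of −0.20 (19 of 20 negative, 0 over the list alone, adjusted p = 0.0196, and adjusted p = 0.764 with an estimated correlation), with Mki67 at −0.08 ± 0.10 SE (+0.01 under quantile normalization) and Top2a at −0.21 ± 0.10 SE, and ended without AR-ASO replicate 2 (adjusted p = 0.188). Homeostatic microglia markers (+0.06) and anterior Hox genes (+0.05) were called higher (adjusted p = 6.42e-05 and 0.00454, and adjusted p = 0.48 with an estimated correlation for both). The first ended without AR-ASO replicate 2 (median +0.019, adjusted p = 0.0929; +0.088 without AR-ASO replicate 1) and the second without AR-97Q replicate 1 (+0.014, 0.0553). REST target genes were not called (median −0.11, adjusted p = 0.267; Syn1 +0.04 ± 0.14 SE, Syp −0.19 ± 0.09 SE).

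By limma, 2 of 16447 genes passed for P7 AR-ASO against AR-97Q. Gpd1, a cytosolic glycerol-3-phosphate dehydrogenase gene on chromosome 15 (99717587 to 99725014), rose from 22.6 ± 1.4 to 43.6 ± 6.0 TPM (+0.92 ± 0.10 SE, adjusted p = 0.0126). Ntm, a neuronal cell adhesion gene on chromosome 9 (28994749 to 29963269), fell from 190 ± 6.5 to 123 ± 8.5 TPM (−0.62 ± 0.08 SE, adjusted p = 0.0433). The next by p did not pass: Lman2l (−0.80 ± 0.12 SE), Mtm1, a phosphoinositide phosphatase gene (−0.93 ± 0.14 SE), and Rab37 (+0.82 ± 0.13 SE). At an unadjusted p under 0.05, 2301 genes passed, 407 higher and 1894 lower, and 3448 (20.96%) had groups without overlap, against 10% on average. The Ntm call ended without any 1 of the 6 libraries compared (adjusted p 0.0651 to 0.206), and the Gpd1 call without AR-97Q replicate 1 (0.0519), 2 (0.108) or 3 (0.06) or AR-ASO replicate 3 (0.0854).

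Against WT, the P7 AR-ASO treated AR-97Q libraries showed no call for myelin genes. The myelinating oligodendrocyte list had a median of −0.03 (adjusted p = 0.214; 1 gene lower over the list alone). Single libraries went both ways for Mbp. It took 1.501% of total TPM in AR-ASO replicate 2, above all P7 WT libraries (1.167% to 1.383%). In AR-ASO replicates 1 and 3 it took 0.976% and 0.939%, between the WT libraries and the AR-97Q libraries (0.5695% to 0.7337%). The absence of a call thus does not show a return to the WT level in each library. Astrocyte markers had a median of −0.18, with 15 of 17 negative and 6 lower over the list alone (adjusted p = 1.98e-09, and adjusted p = 0.43 with an estimated correlation); Aqp4 stood at 0.00 ± 0.09 SE and Aldh1l1 at −0.22 ± 0.09 SE. Motor neuron markers had a median of −0.18 (19 of 23 negative, 2 lower over the list alone, adjusted p = 3.65e-05, and adjusted p = 0.85 with an estimated correlation), with Chat at −0.36 ± 0.14 SE and Slc18a3 at −0.51 ± 0.13 SE. Meningeal fibroblast genes had a median of −0.22 (0 over the list alone; Col1a1 −0.17 ± 0.19 SE, Col1a2 −0.21 ± 0.08 SE) and endothelial and mural markers −0.20 (2 lower over the list alone; Cldn5 −0.10 ± 0.10 SE, Pecam1 −0.14 ± 0.10 SE). Their adjusted p were 0.00713 and 1.32e-05, and adjusted p = 0.43 and 0.466 with an estimated correlation; both ended without AR-ASO replicate 1 (medians −0.13 and −0.063, adjusted p = 0.0868), and the endothelial median was −0.13 without WT replicate 3. The motor neuron median was −0.10 without AR-ASO replicate 2. Interferon-stimulated genes had a median of +0.21 (0 over the list alone, adjusted p = 0.00154, and adjusted p = 0.43 with an estimated correlation; Ifit2 +0.08 ± 0.10 SE, Ifit3 +0.27 ± 0.20 SE), which ended without AR-ASO replicate 2 (adjusted p = 0.0811) and was +0.13 without WT replicate 1. GABA-A and glycine receptor genes (+0.11, adjusted p = 0.0079, and adjusted p = 0.974 with an estimated correlation) ended without WT replicate 1 (+0.0070, adjusted p = 0.498) or AR-ASO replicate 3 (+0.068, 0.0791) and stood at +0.18 without WT replicate 3. REST target genes had a median of +0.05 and were not called (adjusted p = 0.0719).

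By limma, 3 of 16447 genes fell in P7 AR-ASO treated AR-97Q against WT, each at an adjusted p of 0.0167. Ntng2 on chromosome 2 (29194726 to 29248099) fell from 13.1 ± 2.1 to 5.97 ± 0.28 TPM (−1.01 ± 0.12 SE). Setx, the gene of the helicase senataxin, lies beside it on chromosome 2 (29123588 to 29182471) and fell from 15.7 ± 1.5 to 8.83 ± 0.17 TPM (−0.76 ± 0.09 SE). Jam3, a junctional adhesion gene on chromosome 9 (27097384 to 27155421), fell from 46.7 ± 3.5 to 24.9 ± 3.2 TPM (−0.89 ± 0.11 SE). In untreated AR-97Q the means were 6.72 TPM for Ntng2, 10.5 for Setx and 38.3 for Jam3. At an unadjusted p under 0.05, 910 genes passed, 395 higher and 515 lower, and 1717 (10.4%) had groups without overlap, against 10% on average. Each call ended in 5 of the 6 fits that left out 1 library (adjusted p up to 0.153); Ntng2 held only without WT replicate 3, Jam3 without AR-ASO replicate 2 and Setx without WT replicate 1.

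Gdf1 and Cers1 showed the largest differences in assigned TPM between Rest4-ASO and scramble-ASO at P7. Gdf1, a growth factor gene, rose from 2.74 ± 0.64 to 72.5 ± 5.6 TPM (+4.31 ± 0.12 SE, limma adjusted p = 4e-07), and Cers1, a ceramide synthase gene, fell from 83.8 ± 7.1 to 7.62 ± 1.15 TPM (−3.30 ± 0.11 SE, adjusted p = 6.49e-07). They overlap almost wholly on chromosome 8 (70315775 to 70331592 and 70315775 to 70331588), so the division of reads between them is uncertain, and the same opposite levels appeared in 10 of the 21 libraries of other groups, among them all 6 WT and AR-97Q libraries at 13 weeks. The other calls were smaller. H19, an imprinted non-coding RNA, rose from 7.52 ± 3.1 to 23.9 ± 4.6 TPM (+1.59 ± 0.22 SE, adjusted p = 0.0472). Snurf rose by +0.62 ± 0.09 SE (adjusted p = 0.0472) and Snhg14, whose span on chromosome 7 (59272737 to 60450177) includes Snurf, fell by 0.70 ± 0.06 SE on the log2 scale (adjusted p = 0.00512); that overlap leaves the assignment of reads open too.

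**Figure D3:**
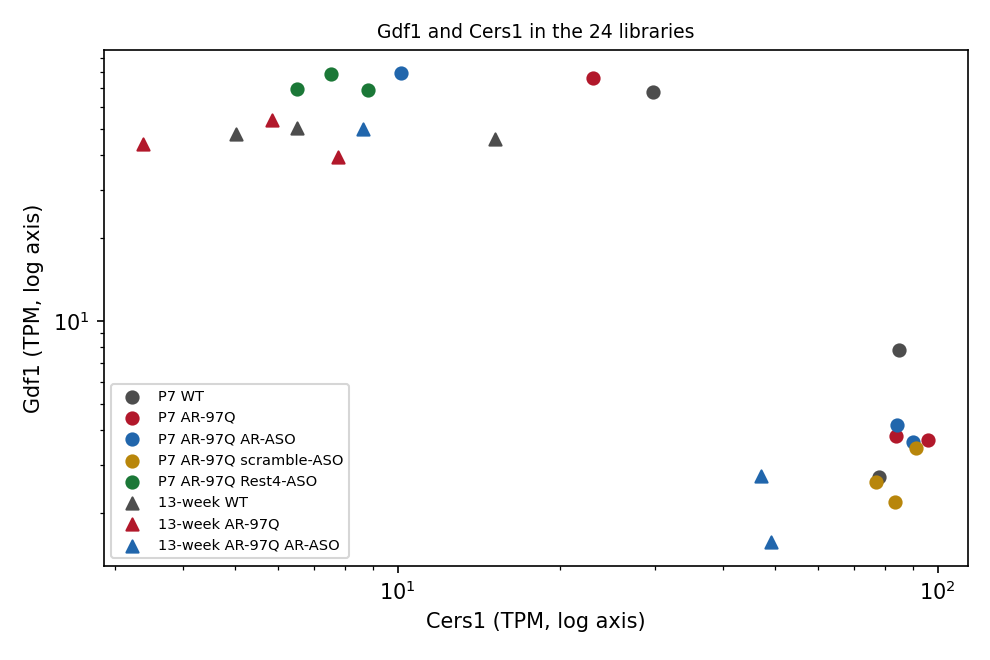
Gdf1 against Cers1 in the 24 libraries, both in TPM on log axes; each point is 1 library, colours mark groups, circles are P7 and triangles 13 weeks. The Rest4-ASO libraries sit at high Gdf1 and low Cers1, as do 10 of the 21 libraries without Rest4-ASO.

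Lower after Rest4-ASO were also the short features Snord14a (−1.78 ± 0.21 SE, adjusted p = 0.0327) and Mir1906-2 (−1.06 ± 0.13 SE, adjusted p = 0.0327), which are uncertain in an mRNA library. Tmc4 (−0.80), Ppp1r35 (−0.71), Dennd6b (−0.59) and Cox6b2 (−0.59), the last a respiratory chain subunit gene, fell at limma adjusted p from 0.0368 to 0.0472, and so did Ndufc1 (−0.47) and the pseudogene Pisd-ps1 (−0.61, adjusted p = 0.0327), both named outside the rule. In all, 13 of 16012 genes passed, 3 higher and 10 lower. Among the 13, the calls of Gdf1 and Cers1 held without each library in turn and Snhg14 was lost only without Rest4-ASO replicate 2 (adjusted p = 0.0643). The other 10 each ended in 5 or 6 of the 6 such fits (adjusted p 0.0585 to 0.187). Leaving out scramble-ASO replicates 1, 2 and 3 in turn gave 6, 4 and 12 calls, of which 4, 4 and 6 were among the 13. Leaving out Rest4-ASO replicates 1, 2 and 3 gave 4, 2 and 7, of which 4, 2 and 3 were. At an unadjusted p under 0.05, 2707 genes passed, 771 higher and 1936 lower, and 3668 (22.9%) had groups without overlap, against 10% on average.

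Lists of lipid synthesis and myelin lay higher after Rest4-ASO. Cholesterol biosynthesis genes had a median of +0.23, with 22 of 23 positive and 5 higher and 1 lower over the list alone (adjusted p = 2.53e-09 by camera, and adjusted p = 0.799 with an estimated correlation); Hmgcr, the rate-limiting enzyme, stood at +0.34 ± 0.07 SE and Hmgcs1 at +0.35 ± 0.10 SE. Myelinating oligodendrocyte genes had a median of +0.45 with 25 of 25 positive, but 0 passed over the list alone and the libraries of the groups overlapped (adjusted p = 2.7e-10, and adjusted p = 0.799 with an estimated correlation). Mbp stood at 9548 ± 4161 TPM after scramble-ASO and 14551 ± 2971 TPM after Rest4-ASO, and Plp1 at 2639 ± 895 and 3673 ± 883 TPM. The myelin median was +0.75 without scramble-ASO replicate 2 and +0.20 without scramble-ASO replicate 3, where the cholesterol median was +0.15. Anterior Hox genes, which mark cervical and brachial levels, had a median of −0.30 with 13 of 14 negative and 8 lower over the list alone (adjusted p = 3.88e-05, and adjusted p = 0.799 with an estimated correlation); Hoxa1 stood at −0.28 ± 0.13 SE and Hoxa2 at −0.23 ± 0.15 SE. Heat shock and chaperone genes had a median of +0.11 (0 over the list alone, adjusted p = 3.88e-05, and adjusted p = 0.799 with an estimated correlation).

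Camera called 10 further lists for Rest4-ASO at adjusted p from 0.00292 to 0.0464, each at adjusted p = 0.799 with an estimated correlation. Higher were erythroid genes (+0.18; Hba-a1 +0.19 ± 0.22 SE, Hba-a2 +0.16 ± 0.21 SE), mitochondrially encoded genes (+0.14, turning to −0.09 under quantile normalization), proliferation (+0.12), homeostatic microglia (+0.08), reactive astrocyte (+0.08), oligodendrocyte precursor (+0.08), astrocyte (+0.05) and unfolded protein response genes (+0.06). Lower were inhibitory interneuron markers (−0.14; Gad1 −0.13 ± 0.08 SE, Gad2 −0.00 ± 0.09 SE, and +0.03 under quantile normalization) and sodium and calcium channel genes (−0.10). All 10 of these calls ended when 1 library was left out, each of the 6 libraries ended at least 1 of them, and the adjusted p then lay between 0.0539 and 0.405. Without Rest4-ASO replicate 3 the erythroid median was +0.049 and the homeostatic microglia median +0.22, and without Rest4-ASO replicate 2 they were +0.39 and +0.050. Without Rest4-ASO replicate 1 the proliferation median was +0.039, that of homeostatic microglia +0.0067 and that of the unfolded protein response +0.0058. Without scramble-ASO replicate 3 the last turned to −0.0030, the astrocyte median was +0.0063, the erythroid median +0.38, that of homeostatic microglia +0.18 and that of proliferation +0.20. Without scramble-ASO replicate 2 the proliferation median was +0.011 the erythroid median +0.075 and that of sodium and calcium channels −0.19. Without scramble-ASO replicate 1 the erythroid median was +0.12 and that of proliferation +0.21. The reactive astrocyte and precursor medians ran from +0.014 and +0.041 (both without Rest4-ASO replicate 2) to +0.13 (scramble-ASO replicate 1) and +0.15 (scramble-ASO replicate 2). Over the fits without 1 library, the unfolded protein response median reached +0.11 and the astrocyte median +0.081. The mitochondrial median ran from +0.094 to +0.21. REST target genes were not called (median −0.05, adjusted p = 0.279; 4 lower over the list alone; Syn1 −0.06 ± 0.07 SE, Syp −0.07 ± 0.07 SE), nor were motor neuron markers (median −0.07, adjusted p = 0.528; Chat +0.14 ± 0.15 SE, Slc18a3 −0.38 ± 0.12 SE).

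At 13 weeks 3 neuropeptide genes rose in AR-97Q against WT. Calca, the gene of calcitonin and the calcitonin gene-related peptide on chromosome 7 (114625981 to 114636910), rose from 59.7 ± 5.3 to 552 ± 95 TPM (+3.18 ± 0.13 SE, limma adjusted p = 0.000191). Ucn, the gene of urocortin on chromosome 5 (31137989 to 31138895), rose from 0.928 ± 0.070 to 19.7 ± 5.0 TPM (+3.39 ± 0.20 SE, adjusted p = 0.00144). Uts2, the gene of urotensin 2 on chromosome 4 (150997097 to 151001810), rose from 36.4 ± 3.2 to 248 ± 83 TPM (+2.69 ± 0.20 SE, adjusted p = 0.00674). Calcb, a close relative of Calca named after its values were seen, did not pass (16.5 ± 0.27 and 45.2 ± 14 TPM, adjusted p = 0.22); how reads were divided between such paralogs is not stated. The Uts2 call ended without WT replicate 1 (adjusted p = 0.0512), 2 (0.0655) or 3 (0.0678) or AR-97Q replicate 1 (0.0691).

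**Figure D4:**
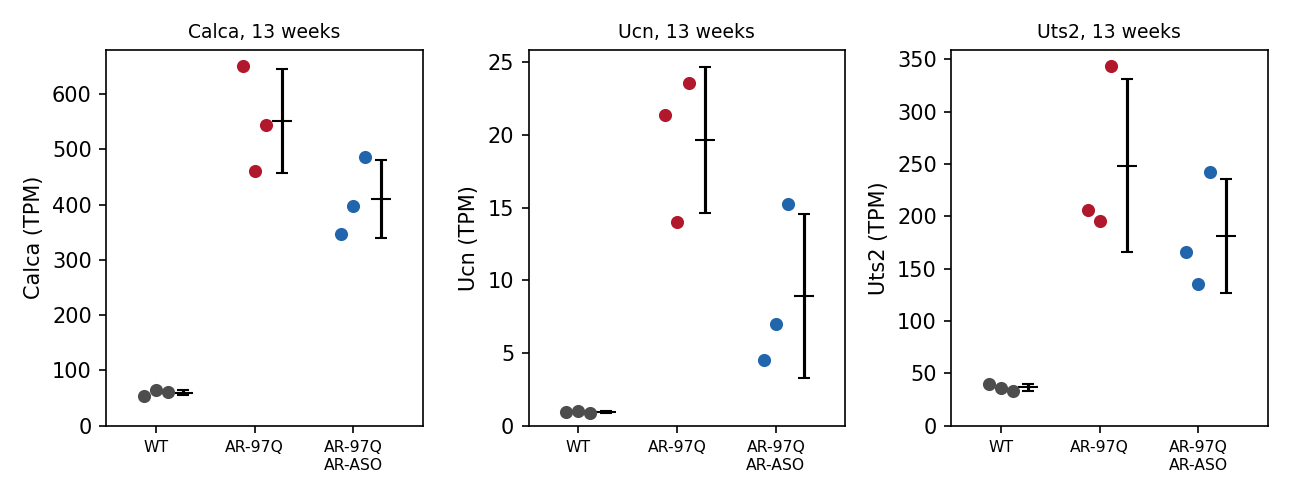
Calca, Ucn and Uts2 in TPM (y axes) in each 13-week library (points) by group (x axis), with mean and SD of 3 libraries. All AR-97Q libraries lie above all WT libraries for each gene; the AR-ASO libraries come from a separate table and stand beside the others without a test.

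Lipid synthesis, chaperone and several glial lists fell in 13-week AR-97Q. Cholesterol biosynthesis genes had a median of −0.33, with 22 of 23 negative and 12 lower over the list alone (adjusted p = 2.07e-08 by camera, and adjusted p = 0.811 with an estimated correlation); Hmgcr stood at 63.2 ± 1.0 TPM in WT and 45.3 ± 1.3 TPM in AR-97Q (−0.47 ± 0.07 SE), and Hmgcs1 at −0.65 ± 0.16 SE. Heat shock and chaperone genes had a median of −0.31, with 14 lower over the list alone (adjusted p = 4.42e-07, and adjusted p = 0.811 with an estimated correlation). Myelinating oligodendrocyte genes had a median of −0.35 (22 of 25 negative, 0 over the list alone, adjusted p = 0.000859, and adjusted p = 0.84 with an estimated correlation), with Plp1 at −0.68 ± 0.19 SE and Mbp at −0.06 ± 0.10 SE. Ependymal and ciliary genes had a median of −0.52 (10 of 11 negative, 5 over the list alone, adjusted p = 0.00153, and adjusted p = 0.811 with an estimated correlation), with Foxj1, a regulator of motile cilia, at −0.23 ± 0.11 SE and Ccdc153 at −0.69 ± 0.23 SE. Homeostatic microglia markers had a median of −0.61 with 20 of 20 negative and 0 over the list alone (adjusted p = 1.07e-06, and adjusted p = 0.84 with an estimated correlation); P2ry12 stood at −0.62 ± 0.41 SE and P2ry13 at −0.52 ± 0.41 SE. Oligodendrocyte precursor markers (−0.22, adjusted p = 0.0101, and adjusted p = 0.811 with an estimated correlation) fell too. AR-97Q replicate 2 stood apart from the others of its group: without it the microglia median was −0.27, the myelin median −0.20, the ependymal median −0.33 and the precursor median −0.14.

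Steroid receptor response genes had a median of +0.40 at 13 weeks (12 of 13 positive, 0 over the list alone, adjusted p = 0.000858, and adjusted p = 0.84 with an estimated correlation), which was +0.21 without AR-97Q replicate 2 and +0.81 without AR-97Q replicate 3. Fkbp5, a co-chaperone of steroid receptors, stood at 16.1 ± 1.3 TPM in WT and 48.1 ± 36 TPM in AR-97Q, and Tsc22d3 at +0.04 ± 0.12 SE. Motor neuron markers had a median of +0.14, with Calca, itself a listed member, called over all genes and 5 higher and 2 lower over the list alone (adjusted p = 0.00412, and adjusted p = 0.791 with an estimated correlation); Chat stood at +0.24 ± 0.10 SE and Slc18a3 at +0.29 ± 0.11 SE. That call ended without AR-97Q replicate 1 (adjusted p = 0.0717), as did that of excitatory interneuron markers (−0.31, adjusted p = 0.00919, adjusted p = 0.84 with an estimated correlation, and 0.0717 without that library, with a median of −0.17). The excitatory median was −0.49 without AR-97Q replicate 3, and the motor neuron median +0.092 without WT replicate 1. Mitochondrially encoded genes (+0.16, adjusted p = 0.0115, a call that ended under quantile normalization) and ribosomal protein genes (+0.05, adjusted p = 0.00412) were called higher, each at adjusted p = 0.84 with an estimated correlation. The first ended without WT replicate 2 (+0.10, adjusted p = 0.133) or AR-97Q replicate 1 (+0.091, 0.777) and the second without WT replicate 1 (+0.031, 0.0813) or AR-97Q replicate 2 (−0.027, 0.775). The second stood at +0.083 without WT replicate 2 and +0.10 without AR-97Q replicate 3. REST target genes were not called (median −0.02, adjusted p = 0.981; Syn1 −0.13 ± 0.12 SE, Syp +0.09 ± 0.07 SE).

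For 13-week AR-97Q against WT, 3 of 16043 genes passed by limma, all higher, and 2203 passed at an unadjusted p under 0.05, 682 higher and 1521 lower. Without AR-97Q replicate 2 the count was 44, with 15 higher and 29 lower, and without AR-97Q replicate 3 it was 9. In 3774 genes (23.5%) the groups did not overlap, against 10% on average. Ar gave +0.17 ± 0.12 SE and Rest +0.42 ± 0.17 SE (limma adjusted p = 0.503 and 0.356). Rest stood at 3.17 ± 0.34 TPM in WT and 4.63 ± 1.06 TPM in AR-97Q. For both genes the groups did not overlap, with an exact permutation p of 0.1, the smallest possible.

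In the 13-week AR-ASO libraries Calca stood at 410 ± 70 TPM, Ucn at 8.91 ± 5.6 TPM and Uts2 at 181 ± 55 TPM. Each mean lay between those of WT and AR-97Q, 13.5%, 34.7% and 16.6% of the way from AR-97Q to WT on the log scale. The AR-ASO and AR-97Q libraries overlapped for each gene. AR-ASO reached 486, 15.2 and 242 TPM, above AR-97Q replicate 2 at 462, 14.0 and 196 TPM in that order. These genes were picked for their rise in the same AR-97Q libraries, so a lower mean in another group could follow from that choice alone. Calcb stood at 46.6 ± 8.9 TPM. Over gene lists, the mean log2(TPM + 1) was 8.52 in WT, 8.09 in AR-97Q and 8.53 in AR-ASO for myelinating oligodendrocyte genes. It was 6.23, 5.86 and 6.26 for cholesterol biosynthesis genes and 4.61, 3.95 and 4.55 for homeostatic microglia markers. AR-97Q replicate 2 lowered these AR-97Q means. For myelin genes it stood at 7.602, against 8.259 and 8.399 in the other AR-97Q libraries. For cholesterol genes it stood at 5.633 against 5.964 and 5.97, and for microglia markers at 3.232 against 4.227 and 4.381. The other AR-97Q libraries still lay below all AR-ASO libraries, whose lowest values were 8.434, 6.193 and 4.469 in that order. Ependymal and ciliary genes stood at 3.70, 3.24 and 3.20 over the 11 members tested (2.93, 2.52 and 2.48 over all 15 measured), motor neuron markers at 5.21, 5.43 and 5.45, and heat shock and chaperone genes at 7.48, 6.95 and 7.13. Plp1 stood at 5838 ± 436 TPM (5638 ± 336 TPM in WT), Hmgcr at 63.2 ± 4.7 TPM (63.2 ± 1.0 TPM in WT) and Ccdc153 at 6.45 ± 2.9 TPM (12.5 ± 1.2 TPM in WT). None of these was tested, since the AR-ASO libraries were in a table of their own.

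The AR-97Q effect differed between the ages for 5 of 17121 genes by limma. Calca, Ucn and Uts2 had a larger effect at 13 weeks (+3.13 ± 0.22 SE, +3.92 ± 0.31 SE and +2.61 ± 0.25 SE, adjusted p = 5.01e-05, 0.000151 and 0.000689), with Calca at +0.05 ± 0.18 SE and Uts2 at +0.08 ± 0.28 SE at P7 (−0.03 and −0.000477 under quantile normalization). Ucn was below the filter at P7 and not tested there, with 0.63 ± 0.40 TPM in WT and 0.11 ± 0.20 TPM in AR-97Q. Spp1, the gene of osteopontin on chromosome 5 (104435111 to 104441053), gave −0.69 ± 0.18 SE at P7 and +0.60 ± 0.08 SE at 13 weeks (difference +1.29 ± 0.17 SE, adjusted p = 0.0175). Ngfr, the p75 neurotrophin receptor gene on chromosome 11 (95568818 to 95587698), gave +0.58 ± 0.14 SE and −0.62 ± 0.17 SE (difference −1.20 ± 0.17 SE, adjusted p = 0.0391). The fit of the difference pools the spread over both ages and leaves out the AR-ASO libraries. Its SE can thus be smaller than that of an effect at a single age, and these calls rest on that pooled spread. The Spp1 call ended in 6 and the Ngfr call in 9 of the 12 fits without 1 library (adjusted p up to 0.0932 and 0.19). Without 13-week AR-97Q replicate 3 the count of genes was 818 and without 13-week AR-97Q replicate 2 it was 26; without P7 WT replicate 2 or 13-week WT replicate 2 it was 3. At an unadjusted p under 0.05, 547 genes were higher and 2375 lower. Quantile normalization moved the median difference of all genes from −0.117 to −0.00225. Camera called 13 of 38 lists, 7 higher and 6 lower, none with an estimated correlation (smallest adjusted p = 0.486), and fry called 5. Without P7 WT replicate 2 or 3, P7 AR-97Q replicate 1 or 13-week AR-97Q replicate 3, camera called 20, 23, 20 and 22. Chat and Slc18a3 gave +0.38 ± 0.17 SE and +0.36 ± 0.15 SE.

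**Figure D5:**
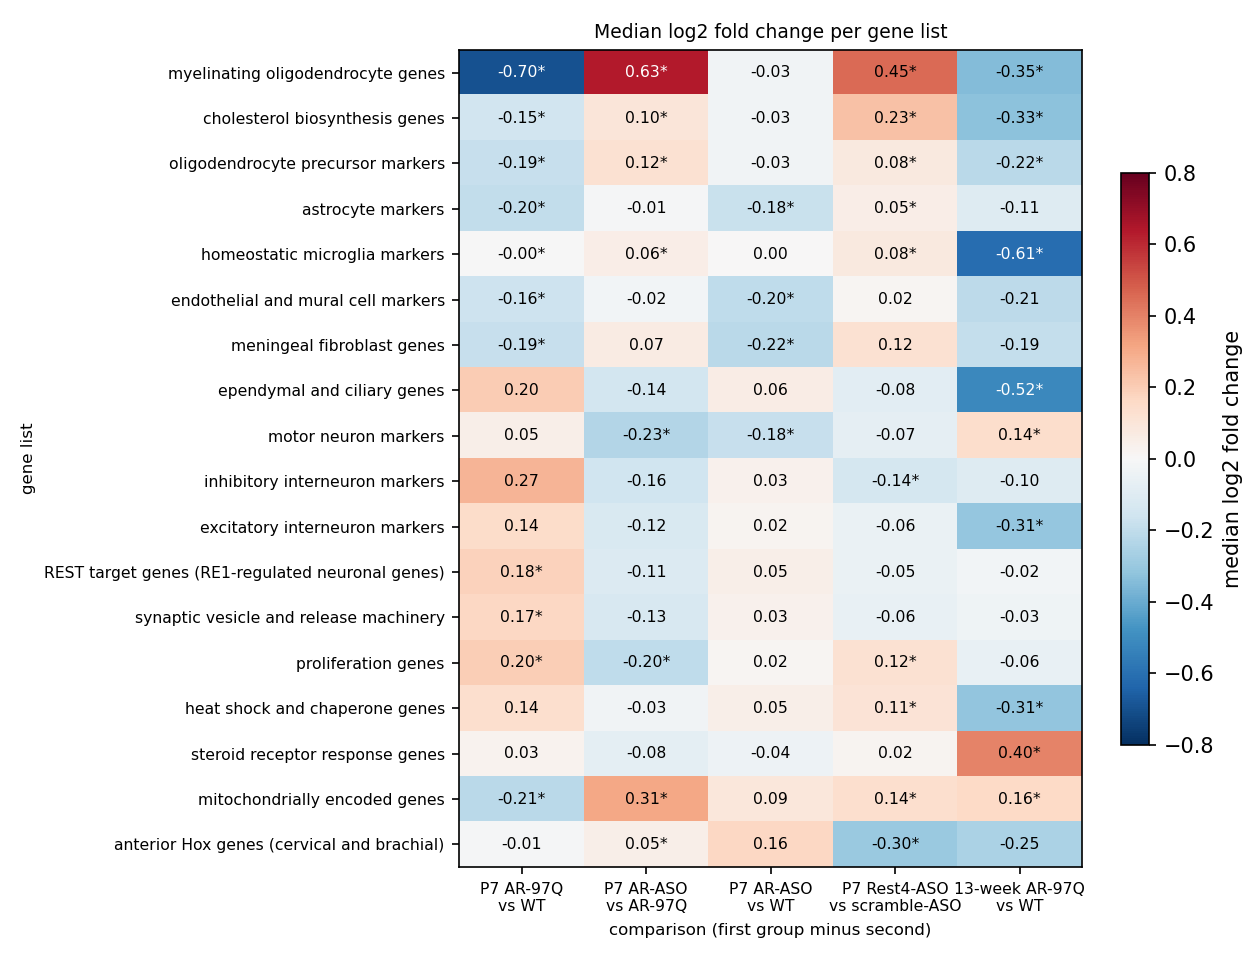
Median log2 fold change of 18 gene lists (y axis) in 5 comparisons (x axis), printed and coloured from blue (lower in the first group) to red (higher); an asterisk marks an adjusted p under 0.05 by camera with the preset correlation. Myelinating oligodendrocyte genes stand at −0.70 in P7 AR-97Q against WT and at +0.63 in AR-ASO against AR-97Q. Both of these comparisons use the same AR-97Q libraries, so the values are not independent.

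Fold changes were compared between comparisons across genes. P7 AR-97Q against WT and AR-ASO against AR-97Q gave a Pearson r of −0.61 over 16447 genes (Spearman rho −0.58), but both use the 3 AR-97Q libraries, and simulated unchanged groups gave a mean r of −0.48 (−0.88 to −0.17). The covariance was −0.0222 against −0.0152 simulated. With these 3 libraries divided between the comparisons, 1 to one and 2 to the other, the 6 ways gave r from −0.287 to −0.00788 and covariances from −0.0141 to −0.000454 (mean −0.00848). These ways overlap and were not tested, and 1 side always held a single AR-97Q library. Among comparisons without shared libraries, AR-ASO against AR-97Q and Rest4-ASO against scramble-ASO gave r = 0.26 (rho 0.32; exact permutation p = 0.09 over splits of both sets, 0.26 after Benjamini-Hochberg adjustment over 4 pairs). P7 AR-97Q against WT gave r = −0.16 with Rest4-ASO (exact permutation p = 0.22, adjusted 0.293) and r = −0.017 with 13-week AR-97Q against WT (exact permutation p = 0.84, adjusted 0.84), and 13-week AR-97Q gave r = −0.15 with Rest4-ASO (exact permutation p = 0.13, adjusted 0.26).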

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

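The tests of nerve root tissue, of Gdf1 and Cers1 and of mislabelled libraries were chosen only after the result was seen. For an AR-ASO treated library under the AR-97Q label, a test of 3 genes (Calca, Ucn and Uts2, all inside the range of the AR-ASO treated libraries) and one of a correlation (mean r = −0.25, with −0.010 to 0.048 for the AR-ASO libraries themselves) were tried before the test of distance given here, and decided nothing.

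The effect of AR-97Q differed between the ages for 5 genes and 13 lists, by limma and camera tests of the difference itself (13 weeks minus P7). For Calca the difference was 3.13, for Ucn 3.92, for Uts2 2.61 and for Spp1 1.29 on the log2 scale, and for Ngfr it was −1.20. Lists with a more negative effect at 13 weeks were homeostatic microglia markers (median −0.52; P2ry12 −0.44, P2ry13 −0.43), ependymal and ciliary genes (−0.52; Foxj1 −0.36, Ccdc153 −0.76) and excitatory interneuron markers (−0.46; Slc17a6 −0.43, Slc17a8 −0.44). Heat shock and chaperone genes (−0.41; Hspa1a −2.14, Hspa1b −2.63), proliferation genes (−0.36) and axon guidance and growth genes (−0.32) also had a more negative effect. More positive were steroid receptor response genes (0.80; Fkbp5 +0.99, Tsc22d3 −0.06, turning to +0.02 under quantile normalization), mitochondrially encoded genes (0.37) and myelinating oligodendrocyte genes (0.24). Astrocyte markers (0.094), meningeal fibroblast genes (0.057), cytosolic ribosomal protein genes (0.058) and motor neuron markers (0.052) were more positive by less. None of the 13 held with an estimated correlation (adjusted p = 0.486 or 0.687).

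Leaving out 1 library ended 5 of these 13 list calls. Without 13-week AR-97Q replicate 2 the microglia median was −0.26 (adjusted p = 0.0533), and without 13-week AR-97Q replicate 1 the excitatory interneuron median was −0.38 (adjusted p = 0.0652). The axon guidance call ended without P7 WT replicate 1 (adjusted p = 0.106), the ribosomal call in 5 of 12 fits (up to 0.497) and the meningeal call in 4 of 12 (up to 0.156).

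Other medians of the difference moved by over 1.5 times when 1 library was left out. The steroid median was 0.25 without 13-week AR-97Q replicate 2. The myelin median was 0.094 without 13-week AR-97Q replicate 1, 0.39 without replicate 2 and 0.14 without replicate 3 of that group. The meningeal median turned to −0.10 without P7 AR-97Q replicate 1, −0.031 without P7 WT replicate 2, −0.035 without 13-week WT replicate 2 and −0.081 without 13-week AR-97Q replicate 3. It was 0.0022 without P7 WT replicate 3, 0.026 without P7 AR-97Q replicate 2, 0.029 without 13-week AR-97Q replicate 1 and 0.10 to 0.11 without 13-week WT replicate 1 or 3 or 13-week AR-97Q replicate 2. The ribosomal median turned to −0.025 without 13-week AR-97Q replicate 2 and −0.0068 without P7 WT replicate 1. It was 0.015 and 0.025 without P7 AR-97Q replicates 2 and 3, 0.029 without 13-week WT replicate 1, and 0.10 and 0.092 without P7 AR-97Q replicate 1 and 13-week AR-97Q replicate 3. The motor neuron median turned to −0.015 without P7 WT replicate 3. It was 0.18 and 0.017 without P7 WT replicates 1 and 2, 0.088 and 0.025 without 13-week WT replicates 2 and 3, and 0.034 without 13-week AR-97Q replicate 1. The astrocyte median was 0.058 and 0.16 without P7 WT replicates 1 and 3 and 0.15 without 13-week AR-97Q replicate 2.

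Among 100 splits of the libraries, 3 gave at least 5 genes, the real one included, a share under 0.05. The other 2 gave 5 and 65 genes. Every split that kept or exchanged all labels at 13 weeks gave at least 3 genes, and no other split gave more than 2. The splits assume no AR-97Q effect at either age. They therefore cannot decide whether a difference between ages lies beyond chance, since an effect at 13 weeks alone raises the count. The split with 65, many times the real count, kept the groups at P7 and exchanged all WT and AR-97Q labels at 13 weeks. It thus measured the sum of the differences between the AR-97Q and WT groups at both ages. The structure it follows is that of these groups, by genotype or by anything else that separates them. The other also exchanged all labels at 13 weeks, with 1 AR-97Q library left in place at P7. For lists, 56 of 100 splits gave as many as the 13 of the real split (highest other 21), so chance cannot be excluded for their number.

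Myelin genes were lower in P7 AR-97Q than in WT, with a list median of −0.70. After quantile normalization the median was −0.75, which argues against a shift in the scaling of the whole library. Genes of Schwann cells and nerve roots differed by −0.056 ± 0.024 SE, against −0.69 ± 0.14 SE for the myelin list, which argues against nerve root tissue in the WT dissections. An earlier developmental stage of the AR-97Q pups stays open and may contribute. It was tested on 17 neuronal genes picked as higher in 13-week WT than in P7 scramble-ASO treated AR-97Q. Their choice thus mixes age with genotype and ASO treatment. They differed by −0.13 ± 0.15 SE between P7 AR-97Q and WT, too wide a spread to decide. An effect of the genotype on myelination stays among the open explanations as well.

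Gdf1 was higher and Cers1 lower after Rest4-ASO, and these genes overlap. The summed TPM of both changed by −0.11 ± 0.091 SE on the log2 scale, in line with reads moved from one gene to the other. In 10 of the 21 libraries without Rest4-ASO, 3 of them among the 12 at P7, Gdf1 exceeded Cers1, which argues against a state that only the Rest4-ASO injection gives. The log2 ratio of Gdf1 to Cers1 fell in separate ranges, with no value between −3.27 and 1.17 in those 21. Whether the assignment of shared reads or a switch of the transcript used sets the range in a library stays open, and no biological explanation was tested.

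In the second 13-week AR-97Q library, which lay apart from the others of its group, Calca, Ucn and Uts2 were at least 4.93 times the highest WT library, which argues against a WT library mislabelled as AR-97Q. Its root mean square log2 distance across genes was at least 0.524 to the AR-ASO treated libraries, against up to 0.312 among these and 0.491 and 0.494 to the other AR-97Q libraries, which argues against an AR-ASO treated library mislabelled as AR-97Q as the cause of its standing apart, though not against a wrong label beside another cause. Its deviation from the other AR-97Q libraries correlated across genes with their difference from WT (mean r = 0.29, from 0.257 and 0.318), as more of the change seen in the other AR-97Q libraries would give. Yet Calca, Ucn and Uts2 were lower in it (462, 14.0 and 196 TPM) than in both others, so these 3 called genes showed less of their change, and the explanation stays open. So does a bias by transcript length, with a Spearman rho of 0.10 across the 94.5% of genes with a length.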

How the results depend on the processing

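Tests chosen only after the result was seen were those at an adjusted p under 0.1, with array weights and without Mir and Snor features. So were quantile normalization and the removal of mitochondrial, haemoglobin and ribosomal protein genes for the difference between ages, scaling, pseudocount, block, single-library fits and a division of shared libraries for correlations, scaling and pseudocount for the 13-week AR-ASO levels, and settings other than the correlation, fry and the block for lists. The count-based tools named before the data were examined were not run, since the tables hold no counts, and those for the 13-week AR-ASO comparison that needed a test were not run. The sequencing depth is unknown, so its limits on low genes such as Ar at P7 could not be computed. The cause was not tested for any change below, apart from fewer libraries where 1 was left out.

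Over 1205 alternatives of called lists, 961 kept their direction and call, 241 kept only the direction and 3 turned, by camera's direction. The median itself changed sign in 19 of the 1205. Over 2140 alternatives of named genes, 1875 kept both, 160 lost a call, 40 gained one and 65 turned. Calca, Ucn, Gdf1 and Cers1 kept their calls in every fit without 1 library. For Gdf1 and Cers1 this does not settle how reads were divided between them. The 13-week AR-ASO means of Calca, Ucn and Uts2 lay between those of WT and AR-97Q in all of their alternatives, 3 of 3 genes. Single AR-ASO and AR-97Q libraries overlapped for each gene. The alternatives reuse the same libraries and genes picked for their rise in AR-97Q, so they cannot show an effect of AR-ASO.

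With an estimated correlation 0 lists were called in each of the 6 comparisons. With fry 0 were called in the P7 comparisons and at 13 weeks, and 5, all lower, for the difference between ages.

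For P7 AR-97Q against WT, array weights called 2869 genes (2246 higher, 623 lower) and the compared groups alone 15 (2 higher, 13 lower). Under quantile normalization mitochondrially encoded genes turned to 0.034, Syn1 to −0.017, Aldh1l1 to −0.046, ND2 to 0.197, Calca to −0.027 and Uts2 to −0.000477. Without mitochondrial, haemoglobin and ribosomal protein genes Syn1 turned to −0.0091 and Aldh1l1 to −0.022. With array weights Calca turned to −0.17 and Uts2 to −0.077.

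For AR-ASO against AR-97Q, quantile normalization called 1 gene, no filter 0, the fit without mitochondrial, haemoglobin and ribosomal protein genes 1, an adjusted p under 0.1 gave 4, array weights 50 and the compared groups alone 1, which was neither Gpd1 nor Ntm. Lists numbered 16 at an adjusted p under 0.1 and 16 with array weights. Rest turned to 0.076 and Mki67 to 0.014 under quantile normalization, Rest to 0.039 without mitochondrial, haemoglobin and ribosomal protein genes, and Syn1 to −0.078 and Cspg4 to −0.13 with array weights.

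For AR-ASO against WT, the replicate block called 0 genes, the compared groups alone 0 and array weights 15; an adjusted p under 0.1 gave 11 lists. No filter called 2 genes, neither of them among the 3 reported. Syp turned to 0.031 under quantile normalization and 0.015 without mitochondrial, haemoglobin and ribosomal protein genes. With array weights Syn1 turned to −0.048, Cldn5 to 0.019 and Ifit2 to −0.029.

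For Rest4-ASO against scramble-ASO, genes called numbered 3 under quantile normalization, 4 with no filter, 46 with the filter of 5 TPM, 6 with a pseudocount of 0.1, 4 with the replicate block, 195 at an adjusted p under 0.1 and 282 with array weights. Lists numbered 9 under quantile normalization, 9 with 5 TPM and 9 with array weights. Mitochondrially encoded genes turned to −0.090 and Gad2 to 0.032 under quantile normalization, and Gad2 to 0.0071 without mitochondrial, haemoglobin and ribosomal protein genes.

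For 13-week AR-97Q against WT, array weights called 13 genes and turned Tsc22d3 to −0.024. For the difference between ages, genes numbered 12 with a pseudocount of 0.1, 3 with the replicate block, 8 without mitochondrial, haemoglobin and ribosomal protein genes, 14 at an adjusted p under 0.1 and 715 with array weights. Lists numbered 25 with no filter and 23 at an adjusted p under 0.1. Tsc22d3 turned to 0.017 under quantile normalization and 0.0052 without mitochondrial, haemoglobin and ribosomal protein genes.

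Quantile normalization moved the share of higher genes at an unadjusted p under 0.05 from 77.0% to 45.5% for P7 AR-97Q against WT, from 17.7% to 55.6% for AR-ASO against AR-97Q, from 28.5% to 47.1% for Rest4-ASO, from 31.0% to 48.7% at 13 weeks and from 18.7% to 50.7% for the difference between ages. The balance of higher and lower genes thus depends on the scaling.

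The replicate numbers were not taken to pair the samples, by the criterion that every same-numbered pair correlates above 0.1 after group means are removed. Among the P7 WT, AR-97Q and AR-ASO libraries 1 of 9 same-numbered pairs did (−0.172 to 0.122). Among the scramble-ASO and Rest4-ASO libraries 1 of 3 did (0.0187 to 0.166), and at 13 weeks 0 of 3 (−0.0761 to −0.0262). Differently numbered scramble-ASO and Rest4-ASO pairs ran from −0.119 to 0.0368, lower on balance than the same-numbered ones, so pairing is not excluded there. The replicate block is given here alone.

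Without 1 library, genes called ranged from 0 to 3 for P7 AR-97Q against WT, 0 to 1 for AR-ASO against AR-97Q, 0 to 3 for AR-ASO against WT, 2 to 12 for Rest4-ASO, 2 to 44 at 13 weeks and 3 to 818 for the difference between ages. Lists ranged from 10 to 18, 6 to 14, 7 to 12, 6 to 16, 9 to 16 and 11 to 23 in that order. For P7 AR-97Q against WT, synaptic vesicle genes ranged from 0.023 to 0.24, Rest from −0.076 to 0.021, Syn1 from −0.12 to 0.15, Slc18a3 from −0.14 to 0.028, Aldh1l1 from −0.035 to 0.097 and Calca from −0.090 to 0.20. For AR-ASO against AR-97Q, Rest ranged from −0.082 to 0.026, Syn1 from −0.075 to 0.095, Cspg4 from −0.14 to 0.11 and Mki67 from −0.16 to 0.00232. For AR-ASO against WT, Ar ranged from −0.16 to 0.042, Syn1 from −0.085 to 0.18, Syp from −0.088 to 0.045 and Aqp4 from −0.070 to 0.059. For Rest4-ASO, Ar ranged from −0.12 to 0.017, Rest from −0.091 to 0.12, Gad2 from −0.083 to 0.078 and Hba-a2 from −0.012 to 0.39. At 13 weeks, Mbp ranged from −0.14 to 0.028, P2ry13 from −0.80 to 0.023 and Tsc22d3 from −0.024 to 0.15. For the difference between ages, P2ry12 ranged from −0.76 to 0.12, P2ry13 from −0.72 to 0.11 and Tsc22d3 from −0.13 to 0.046.

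The r of P7 AR-97Q against WT with AR-ASO against AR-97Q ranged from −0.711 to −0.483 without 1 library, and was −0.00788, −0.287 and −0.216 with AR-97Q replicate 1, 2 or 3 alone in the first, and −0.0735, −0.228 and −0.180 with that one alone in the second. The r of P7 AR-97Q against WT with Rest4-ASO ranged from −0.283 to −0.0332 (0.116 over called genes). The r with 13 weeks ranged from −0.0525 to 0.0290 (0.0396 with 5 TPM). The r of both ASO comparisons ranged from 0.140 to 0.354 (0.370 with 5 TPM, 0.157 over called genes), and that of 13 weeks with Rest4-ASO from −0.197 to −0.0811 (0.129 over called genes).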

Other observations

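The test of a correlation between both ASO responses was chosen only after the result was seen.

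The second 13-week AR-97Q library differed from the other libraries of its group in several lists. Relative to their mean, erythroid genes had a median of −2.61 on the log2 scale, homeostatic microglia markers −1.16, interferon-stimulated genes −0.64 and myelinating oligodendrocyte genes −0.63. Steroid receptor response genes had a median of +1.496, reactive astrocyte genes +0.36 and Schwann cell and nerve root genes +0.18. Stress lists went both ways, with p53 target genes at +0.29, heat shock and chaperone genes at −0.07, unfolded protein response genes at −0.14 and immediate early genes at −0.26, and astrocyte markers stood at −0.036. Among single genes Ccn1 stood at +3.61, Cdkn1a at +2.84 and Maff at +2.78. These 3 genes were chosen after their values were seen, and a single library allows no test.

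Fold changes of AR-ASO against AR-97Q and of Rest4-ASO against scramble-ASO at P7 correlated across genes (r = 0.26). The scramble-ASO group was given an ASO too, so only the AR-ASO comparison sets an ASO against none. A response in common to both injections was tested by splitting both sets of libraries anew: 18 of 200 splits gave an r as large in size. That is more than 5% of splits, and r lies above 0. An effect of injection or of any ASO would cancel in Rest4-ASO against scramble-ASO. The correlation therefore could not decide a response to injection as such, and the hypothesis stays open. The criterion for this test was changed after its result was known.

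Ntng2 and Setx, which fell in P7 AR-ASO treated AR-97Q against WT, are neighbours on chromosome 2. Chromosome segments of another strain that differ between the groups could give such neighbours. Among the 100 genes of smallest p, 15 pairs lay within 1 Mb of each other, against a median of 8 and a 95th percentile of 13 in 1000 random draws, of which 30 gave as many. By the criterion as first written, this would count for the hypothesis. Other splits of the same 6 libraries gave up to 26 pairs, and 3 of the other 9 gave at least 15, so the verdict was tightened to open after the result was seen. The same count was 10 for AR-97Q against WT, 14 for AR-ASO against AR-97Q, 14 for Rest4-ASO against scramble-ASO, 24 for 13-week AR-97Q against WT and 7 for the difference between ages. At 13 weeks 0 of 1000 draws gave as many (highest 21), and other splits were not counted for it. The draws giving as many were 283, 49, 67 and 695 for the other 4 in that order.

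The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. For P7 AR-97Q against WT the real split called 0 genes and the highest other 4, and 14 and 21 lists. All 10 splits thus gave as many genes and 5 as many lists. For AR-ASO against AR-97Q the real split called 2 genes (highest other 5) and 8 lists (highest other 14), with 2 and 7 splits as large. For AR-ASO against WT it called 3 genes (highest other 7) and 6 lists (highest other 18), with 2 and 10 splits as large. For Rest4-ASO against scramble-ASO it called 13 genes (highest other 1) and 14 lists (highest other 22), with 1 and 2 splits as large, the real one included. For 13-week AR-97Q against WT it called 3 genes (highest other 0) and 11 lists (highest other 15), with 1 and 4 splits as large.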
